A study of Mus musculus with 31 samples.

How the data were processed

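Translating ribosome affinity purification was used on the entire cortex or on striatum of mice aged 6 weeks or 2 years, and RNA bound to tagged ribosomes of Drd1a- or Drd2-expressing cells was hybridised to 31 mouse exon arrays after fragmentation and biotin labelling with the Encore Biotin Module, per the labels. Groups were taken from the sample labels: 8 combinations of age, region and cell type with 4 arrays each, except young striatum Drd1a with 3. Per the submitters' processing notes the arrays were processed with RMA (robust multi-array averaging) on genome build mm8; version numbers are not given in the sources used here. The deposited values are on the log2 scale, each feature relative to its own median over the arrays (0 within 1e-06 for 16341 of 16345 features), so no absolute level is kept and a signal over background was not computed. In 3 deposited columns the unit is recorded as other, because each holds 1 value with no decimal point. These 3 cells and 1 empty cell were set to missing, and the remaining values ran from -5.08 to 4.59.

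Features were named from the platform's gene table. Of the 16345 features 14793 carried 1 gene symbol, 814 carried several and 738 were not listed. This gave 14769 distinct genes, 14744 of them matched by Entrez identifier to a RefSeq table, which was used for names and for neighbouring genes and not for coordinates. The planned rule for the 24 genes with more than 1 feature, the highest mean, could not be applied to centred values, and the lowest feature number was used. Predicted genes, clones, small RNAs and chemosensory receptors (1297 features) were counted but not named.

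Changes were tested with limma 3.58.1 in R 4.3.3 on all 31 arrays, with 1 mean per group, 23 residual degrees of freedom, and empirical Bayes moderation (prior degrees of freedom 4.68, common residual SD 0.126). The median standard error of an age change was 0.0987 for 4 arrays against 4 and 0.107 for 4 against 3. Tests were two-sided, and a feature was called where the Benjamini-Hochberg adjusted p over all 16345 features was under 0.05 and the change was at least 1.2-fold, the thresholds the submitters state for the 4 age comparisons. The submitters' test is not given in the sources used here. Interactions between age and cell type, interactions between age and region, and the difference between Drd1a and Drd2 cells at each age and region were tested in the same model. Features called in all 4 age comparisons were counted, and pairs of comparisons were compared with Fisher's exact test.

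Of 36 gene lists, 34 with at least 3 measured genes were tested with camera at a preset correlation of 0.01, on 1 feature per gene, with Benjamini-Hochberg adjustment over the lists. For each list limma's p-values were also adjusted over the list alone. Lists, tests, thresholds and the rule for naming genes were chosen before the data were examined. The rule named, for an age comparison, the 10 largest rises and the 10 largest falls among called genes without overlap between old and young arrays, up to 3 called members of each list with the largest change, and Drd1 and Drd2. For interactions it named the 5 largest called changes each way, or the 5 smallest p-values where nothing was called. For the cell type comparisons it named the 5 largest differences each way and up to 3 called pathway and layer markers per list. The genes called in all 4 age comparisons were named as well.

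Each result was recomputed under alternatives: quantile normalization, centring each array on its median, only the groups compared in the fit, a replicate block, cortex and striatum arrays of the same number as a random block, array weights, limma-trend with robust moderation, the first residual component as a covariate, a 1.5-fold threshold, no fold threshold, an estimated correlation or fry for lists, and each array left out in turn. Quantile normalization was applied to the deposited values, which had already been processed with RMA and centred per feature. Leaving out the 6 arrays whose median exceeded 0.05 was added after the array medians had been seen. A filter on dim features needs an absolute level, and a sex covariate needs sex-linked transcripts that part the arrays within groups; neither was run. Tested on simulated data, in which genes were raised or lowered by known folds, the model called 16.4% of 1.2-fold, 74.6% of 1.5-fold and 98.5% of 2-fold changes with 8 unchanged features called in the cortex Drd2 design, and 16.4%, 77.6% and 95.5% with 10 unchanged features in the striatum Drd1a design. The simulated noise was independent between genes. The real arrays share a component that holds 30.1% of the residual variance, so these rates need not hold for them.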

Results

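RNA bound to tagged ribosomes was purified from mouse cortex or striatum by translating ribosome affinity purification, a method that captures the messages being translated in a genetically marked cell type. The marked cells expressed the dopamine receptor gene Drd1a (listed as Drd1, feature 6813284) or Drd2 (feature 6988976), and the mice were 6 weeks or 2 years old. The 31 arrays fell into 8 groups of age, region and cell type, with 4 arrays in each group except the young striatum Drd1a group, which held 3. The number of arrays limits the precision: the median standard error of an age change was 0.099 on the log2 scale for 4 arrays against 4 and 0.11 for 3 against 4. The labels do not say whether replicates came from separate mice, so p-values measure the spread between these samples. Array medians ran from -0.072 to 0.13, and 6 arrays lay above 0.05.

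The receptor genes followed the labels. Drd1 lay at 1.63 ± 0.095 (SD, n = 3) in young striatum Drd1a arrays and at -2.75 ± 0.27 (SD, n = 4) in young striatum Drd2 arrays, in log2 units around its own median. Drd2 lay at -3.46 ± 0.66 (SD, n = 3) in young striatum Drd1a arrays and at 0.49 ± 0.044 (SD, n = 4) in young striatum Drd2 arrays. In cortex at 6 weeks Drd1 was 3.47 log2 units higher in Drd1a arrays, and Drd2 was lower there by a log2 difference of -4.76.

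**Figure D1:**
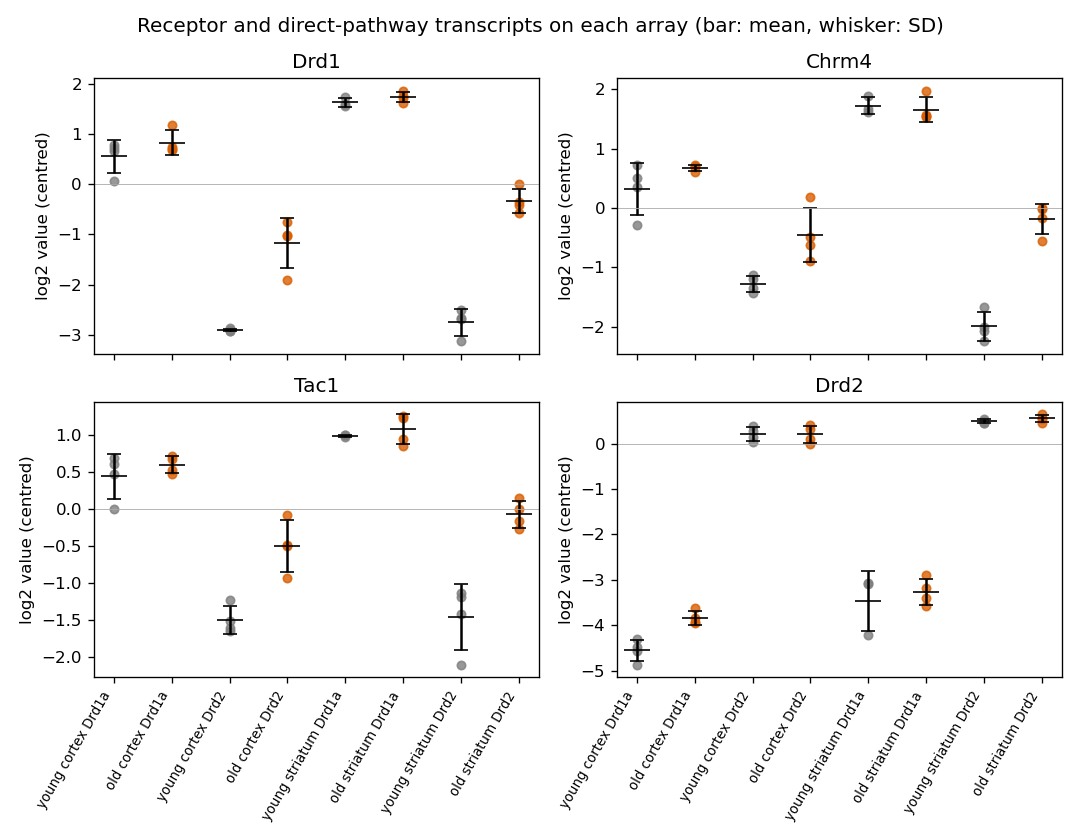
Log2 values of Drd1, Chrm4, Tac1 and Drd2 on every array, each centred on the gene's median over the 31 arrays, by age, region and cell type (points: arrays; bar and whisker: mean and SD). Drd1 rose from -2.75 to -0.34 between young and old striatum Drd2 arrays, while in striatum Drd1a arrays it lay at 1.63 and 1.74.

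The first question was what changed with age in RNA prepared from Drd2-expressing cells of the striatum. RNA of other cells in these preparations could not be excluded as a source of the rise of direct-pathway markers, as set out below. Drd1, the D1 dopamine receptor gene, rose 5.33-fold (log2 change 2.41 ± 0.18 SE, n = 4 per age, adjusted p = 1.75e-09), and so did Chrm4, the M4 muscarinic receptor of direct-pathway neurons, by 3.5-fold (1.81 ± 0.18 SE). Drd2 itself had a log2 change of 0.061 ± 0.17 SE and was not called. B2m, the light chain of MHC class I, rose 4.15-fold (2.05 ± 0.17 SE), Pcdhb8, a clustered protocadherin, 4.55-fold (2.19 ± 0.28 SE), and Kcnj3, a subunit of G protein-gated potassium channels, 3.12-fold (1.64 ± 0.14 SE). Rnd3, a regulator of the actin cytoskeleton, fell 2.74-fold (-1.46 ± 0.20 SE), Egr2, an activity-induced transcription factor, 2.55-fold (-1.35 ± 0.31 SE), and Nts, the neurotensin precursor, 2.53-fold (-1.34 ± 0.27 SE).

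Of the 16345 features, 932 passed an adjusted p of 0.05 and a 1.2-fold change in striatum Drd2 cells, 445 higher and 487 lower at 2 years (419 and 362 with arrays centred on their medians, 293 and 352 with quantile normalization). Further large rises were those of Gpr149, an orphan receptor (3.03-fold, 1.60 ± 0.16 SE), Sulf1, a heparan sulfate endosulfatase (2.99-fold, 1.58 ± 0.13 SE), and Pea15a, a death effector domain phosphoprotein (2.96-fold, 1.56 ± 0.13 SE). Trf, the transferrin gene, and Apod, apolipoprotein D, both abundant in oligodendrocytes, rose 2.9-fold and 2.79-fold. Among the falls were Clspn, a replication checkpoint adaptor (-1.25 ± 0.25 SE), the chromatin organiser Satb1 (-1.07 ± 0.14 SE), the linker histone gene H1f2 (-1.04 ± 0.19 SE), and the corepressor Bcor (-0.97 ± 0.16 SE). Zmat4, Ubash3b and Mcts2 fell as well, by 2.0-fold, 1.98-fold and 1.92-fold. With quantile normalization the log2 changes of Drd1, Kcnj3 and Gpr149 were 1.83, 1.04 and 2.26, and their calls stood.

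In striatum Drd2 cells 12 of 34 gene lists shifted, 8 up and 4 down, and 5 of these calls held with an estimated correlation. The fry test, which asks whether a list's genes move on balance one way without comparing them with other genes, called 10 of the 12. Of 8 direct-pathway neuron markers, 6 rose and 2 were not called (7 rose adjusted over the list alone), with a median log2 change of 0.95 (adjusted p = 4.33e-15, and adjusted p = 0.000293 with an estimated correlation). Tac1, the substance P precursor, rose 2.62-fold (1.39 ± 0.17 SE), whereas Eya1 at 0.34 ± 0.13 SE and Pdyn at 0.14 ± 0.16 SE, named after their values were seen, were the members not called. Of 22 clustered protocadherins, cell-surface adhesion proteins of neurons, 7 rose, 15 were not called and 11 rose adjusted over the list alone (adjusted p = 0.00536 with an estimated correlation), among them Pcdhb6 (1.19 ± 0.18 SE) and Pcdhb14 (0.98 ± 0.12 SE). Of 28 lysosomal genes 9 rose and 19 were not called, with 12 risen adjusted over the list alone (adjusted p = 0.0382 with an estimated correlation). They included Psap, the prosaposin gene (0.71 ± 0.083 SE), Grn, the progranulin gene (0.66 ± 0.090 SE), and Scarb2, a lysosomal membrane protein (0.67 ± 0.18 SE). Of 18 cholesterol biosynthesis genes 5 rose and 13 were not called, with 7 risen adjusted over the list alone (adjusted p = 0.0421 with an estimated correlation), led by Stard4, a sterol carrier (0.87 ± 0.13 SE), and the sterol enzymes Sc5d (0.65 ± 0.15 SE) and Msmo1 (0.57 ± 0.13 SE). Of 70 mitochondrial ribosomal protein genes 15 fell and 55 were not called, with 19 fallen adjusted over the list alone (median -0.18, adjusted p = 0.0277 with an estimated correlation).

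The other 7 list calls in striatum Drd2 cells were lost with an estimated correlation. Of 22 immediate early genes, which neuronal activity induces, 6 fell and 16 were not called, and 6 fell adjusted over the list alone (median -0.20, adjusted p = 0.205 with an estimated correlation). Beside Egr2 they included Nr4a1 (-0.96 ± 0.25 SE) and Egr3 (-0.83 ± 0.19 SE). Of 61 oxidative phosphorylation subunits 6 fell and 55 were not called, with 6 fallen adjusted over the list alone (adjusted p = 0.19 with an estimated correlation), for example Uqcr11 of complex III (-0.37 ± 0.077 SE) and Atp5d of ATP synthase (-0.34 ± 0.061 SE). Of 28 synaptic vesicle release genes 7 rose and 21 were not called, and adjusted over the list alone 8 rose and 1 fell (adjusted p = 0.167 with an estimated correlation), led by Syt4, a synaptotagmin (0.69 ± 0.089 SE). Of 16 oligodendrocyte and myelin markers 2 rose, Trf and Apod, and 14 were not called, with 4 risen adjusted over the list alone (median 0.16, adjusted p = 0.348 with an estimated correlation). The cortical upper-layer markers (2 of 11 risen, 3 adjusted over the list alone) and the complement and MHC class I genes (1 of 11 risen, 1 adjusted over the list alone) shifted up, each with adjusted p = 0.348 with an estimated correlation. None of 35 proteasome subunits was called by limma, over all features or adjusted over the list alone, and their list shifted down (median -0.077, adjusted p = 0.348 with an estimated correlation). Astrocyte markers, not shifted as a list (adjusted p = 0.0946), had 3 of 15 members risen, among them Gfap, the glial filament protein (0.74 ± 0.23 SE). With only these 8 arrays in the fit 469 features were called, and 50 of the 72 genes picked by the fixed rule kept their call whichever array was left out.

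The same question in Drd2-expressing cells of the cortex gave 594 called features, 303 higher and 291 lower at 2 years, against 354 and 177 with arrays centred on their medians and 597 and 389 with quantile normalization. Trf rose 4.58-fold (log2 change 2.20 ± 0.26 SE, n = 4 per age, adjusted p = 2.14e-05), and Drd1 rose 3.32-fold (1.73 ± 0.18 SE, adjusted p = 1.8e-06). Il33, an alarmin cytokine, rose 2.53-fold (1.34 ± 0.21 SE), and 3 genes strongly expressed by astrocytes rose with it: Aldoc, a glycolytic aldolase (2.45-fold), Gfap (2.31-fold), and Glul, glutamine synthetase (2.27-fold). The glial rise was uneven: the astrocyte markers averaged 0.52, 0.31, 0.089 and -0.013 in old replicates 1 to 4, against -0.14 to 0.045 in the young arrays, and Gfap ran from -0.25 to 1.64 in the old arrays. Nts fell 2.29-fold (-1.20 ± 0.27 SE), Tnnc1, a troponin C gene, 2.27-fold (-1.19 ± 0.27 SE), and Clspn 1.94-fold (-0.96 ± 0.25 SE).

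Drd2 had a log2 change of -0.0080 ± 0.17 SE in cortex Drd2 cells and was not called. Other large rises there were those of Apod (2.52-fold), Ermn, a cytoskeletal protein of myelinating oligodendrocytes (2.22-fold), Gstm3, a glutathione transferase (2.08-fold), and Tac1 (2.0-fold). B2m (1.88-fold) and the transcription factor gene Foxp2 (1.86-fold) rose too. Among the falls were Dusp14, a dual-specificity phosphatase (1.81-fold), Rgs4, a regulator of G protein signalling (1.66-fold), Marcksl1, an actin-binding protein of immature neurons (1.66-fold), and Cacng2, the AMPA receptor auxiliary subunit stargazin (1.64-fold). Mcts2, Mro and Crabp1 fell 1.73-fold, 1.67-fold and 1.64-fold. With quantile normalization the log2 changes of Trf, Tac1, B2m, Foxp2 and Chrm4 were 3.04, 2.30, 1.52, 1.64 and 1.51, and their calls stood.

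In cortex Drd2 cells 17 of 34 lists shifted, 12 up and 5 down, and with an estimated correlation 1 call held, that of the direct-pathway markers. Of these 8 genes 4 rose and 4 were not called, with 5 risen adjusted over the list alone (median 0.58, adjusted p = 0.00486 with an estimated correlation), Chrm4 among them (0.83 ± 0.18 SE). Of 16 oligodendrocyte and myelin markers 6 rose and 10 were not called, with 7 risen adjusted over the list alone (median 0.38, adjusted p = 0.136 with an estimated correlation). Of 15 astrocyte markers 4 rose and 11 were not called, and adjusted over the list alone 7 rose and 1 fell (adjusted p = 0.259 with an estimated correlation). Of 28 lysosomal genes 2 rose, Psap (0.34 ± 0.083 SE) and the galactosidase gene Glb1 (0.53 ± 0.14 SE), and 26 were not called, with 7 risen adjusted over the list alone (adjusted p = 0.136 with an estimated correlation). Of 18 cholesterol biosynthesis genes Cyp51 alone rose and 17 were not called, with 4 risen adjusted over the list alone (adjusted p = 0.136 with an estimated correlation). Of 22 clustered protocadherins 2 rose, 1 fell and 19 were not called, and adjusted over the list alone 8 rose and 1 fell (adjusted p = 0.13 with an estimated correlation). Pcdhb6 was at 0.79 ± 0.18 SE and Pcdhb16 at -0.49 ± 0.14 SE.

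Lists that shifted down in cortex Drd2 cells were those of mitochondria, cytosolic ribosomes, activity genes and general striatal neurons. Of 70 mitochondrial ribosomal protein genes 7 fell and 63 were not called, with 12 fallen adjusted over the list alone (median -0.15, adjusted p = 0.136 with an estimated correlation), including Mrpl52 (-0.38 ± 0.087 SE). The list averaged -0.23, -0.14, -0.11 and -0.023 in old replicates 1 to 4, against -0.019 to 0.064 in the young arrays. It was thus lowest in the replicates where the astrocyte markers were highest, and a link was not tested. Of 61 oxidative phosphorylation subunits 4 fell and 57 were not called, with 5 fallen adjusted over the list alone (adjusted p = 0.259 with an estimated correlation), including Uqcr11 (-0.40 ± 0.077 SE). Their means in old replicates 1 to 4 ran in the same order, at -0.17, -0.099, -0.060 and -0.044. Of 42 cytosolic ribosomal protein genes 2 fell, Rpl34 (-0.33 ± 0.063 SE) and Rps3 (-0.27 ± 0.066 SE), and 40 were not called, with 3 fallen adjusted over the list alone (adjusted p = 0.259 with an estimated correlation). Of 22 immediate early genes Homer1 (-0.50 ± 0.097 SE) and Fosl2 (-0.30 ± 0.087 SE) fell and 20 were not called, with 5 fallen adjusted over the list alone (adjusted p = 0.379 with an estimated correlation). None of 14 general striatal projection neuron markers was called by limma, over all features or adjusted over the list alone (median -0.15, adjusted p = 0.407 with an estimated correlation). The remaining 6 called lists, all up, had between 0 and 1 members risen, with adjusted p = 0.259 to adjusted p = 0.464 with an estimated correlation. They were the cholinergic, upper-layer cortical, interferon-induced, circadian clock, protein folding stress and synaptic vesicle release genes, and the clock list also had Arntl fallen (-0.42 ± 0.10 SE). Adjusted over the list alone, 1 cholinergic, 1 vesicle release and 2 clock genes rose and 2 clock genes fell. Without old replicate 1 the medians of the cholinergic and interferon-induced lists were -0.021 and -0.0053, and both calls were lost. With only the 8 arrays of this comparison in the fit 55 features were called. The count was 176 without old replicate 1, 299 without young replicate 2, 334 without young replicate 3 and 345 without old replicate 2, and 24 of the 54 genes picked by the fixed rule kept their call whichever array was left out.

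In Drd1a-expressing cells of the striatum, S100a10, the annexin A2 partner p11, rose 2.82-fold with age (log2 SE 0.21, 4 old against 3 young arrays, adjusted p = 0.000162). Dpp10, an auxiliary subunit of A-type potassium channels, rose 2.3-fold (1.20 ± 0.16 SE), Tnnt2, the cardiac troponin T gene, 2.19-fold (1.13 ± 0.11 SE), and Irak3, a brake on Toll-like receptor signalling, 2.15-fold (1.11 ± 0.12 SE). Rnd3 fell 2.27-fold (-1.18 ± 0.21 SE), Glra2, the glycine receptor alpha-2 subunit of immature neurons, 2.09-fold (-1.06 ± 0.16 SE), and Fabp7, a fatty acid-binding protein of radial glia and astrocytes, 2.07-fold (-1.05 ± 0.26 SE). The GABA receptor subunit genes went both ways: Gabra3 rose 2.06-fold and Gabra5 fell 2.04-fold. Drd1 had a log2 change of 0.11 ± 0.19 SE and Drd2 of 0.20 ± 0.19 SE, and neither was called.

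In total 561 features were called in striatum Drd1a cells, 258 higher and 303 lower at 2 years, a balance that turned to 364 and 170 with arrays centred on their medians and to 270 and 174 with quantile normalization. Plekha2 (2.28-fold), Abi3bp (2.23-fold), Pla2g7, a lipoprotein-associated phospholipase (2.2-fold), Klhl4 (2.15-fold), Cd52, a leukocyte surface antigen (2.11-fold), and B2m (2.07-fold) made up the rest of the largest rises. Ccnd2, a cyclin of dividing progenitors, fell 1.96-fold (-0.97 ± 0.15 SE), Spink10 2.03-fold, Pantr1 1.78-fold, Crabp1, a retinoic acid-binding protein, 1.7-fold and Marcksl1 1.68-fold.

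In striatum Drd1a cells 8 of 34 lists shifted, 5 up and 3 down, and none of these calls held with an estimated correlation. The count of lists was 4 without young replicate 2 and 5 without old replicate 1, and the median of the vesicle release list was -0.014 without old replicate 3. Of 70 mitochondrial ribosomal protein genes 14 fell and 56 were not called, with 23 fallen adjusted over the list alone (median -0.20, adjusted p = 0.0782 with an estimated correlation). Mrpl36 was at -0.60 ± 0.11 SE and Mrpl12 at -0.48 ± 0.092 SE. Of 61 oxidative phosphorylation subunits 8 fell and 53 were not called, with 9 fallen adjusted over the list alone (median -0.14, adjusted p = 0.268 with an estimated correlation), including Atp5g1 (-0.53 ± 0.092 SE) and Ndufa7 of complex I (-0.43 ± 0.078 SE). None of 42 cytosolic ribosomal protein genes was called by limma, and 1 fell adjusted over the list alone (adjusted p = 0.879 with an estimated correlation). Of 30 protein folding stress genes 3 rose and 27 were not called, and adjusted over the list alone 3 rose and 1 fell (adjusted p = 0.245 with an estimated correlation). The risen ones were the co-chaperone Stip1 (0.52 ± 0.078 SE), the endoplasmic reticulum chaperone Hspa5 (0.42 ± 0.098 SE) and Hsph1 (0.32 ± 0.080 SE). Of 28 synaptic vesicle release genes Syt4, Sv2a and Nsf rose and 25 were not called, with 4 risen adjusted over the list alone (adjusted p = 0.374 with an estimated correlation). Of 28 lysosomal genes Psap alone rose (0.51 ± 0.090 SE), over all features and adjusted over the list alone, with 27 not called (adjusted p = 0.397 with an estimated correlation). Of 16 clock genes Nfil3 (0.72 ± 0.13 SE) and Npas2 (0.36 ± 0.085 SE) rose, 2 also adjusted over the list alone, with 14 not called (adjusted p = 0.397 with an estimated correlation). Of 4 indirect-pathway markers Penk, the enkephalin precursor, rose (0.38 ± 0.092 SE), 1 also adjusted over the list alone, with 3 not called (adjusted p = 0.374 with an estimated correlation). The direct-pathway markers were not shifted (median 0.080, adjusted p = 0.51), with 0 of 8 members called.

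In old striatum Drd1a replicate 2 the choroid plexus markers averaged 0.81 on the log2 scale, against -0.086 to -0.038 in the other 3 arrays, and its array median was 0.13. Without this array and the other 5 arrays with a median above 0.05, 429 features were called in striatum Drd1a cells, 300 of them also called on all arrays. Of the 55 genes picked by the fixed rule 40 kept their call, Rnd3, Glra2 and Tnnt2 included. The count was 73 with only these 7 arrays in the fit, 170 without young replicate 1, 259 without young replicate 3 and 311 without old replicate 3. Of the same 55 genes 30 kept their call whichever array was left out.

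Drd1a-expressing cells of the cortex had the lowest count of the 4 age comparisons, 74 features, 35 higher and 39 lower at 2 years (27 and 40 with arrays centred on their medians, 15 and 8 with quantile normalization). Tnnt2 rose 1.9-fold (log2 change 0.92 ± 0.11 SE, n = 4 per age, adjusted p = 1.84e-05), Casp1, the inflammasome protease, 1.8-fold (0.85 ± 0.10 SE), Psmc3ip, a meiotic recombination factor, 2.48-fold (1.31 ± 0.19 SE), and Defb1, a beta-defensin, 2.04-fold (1.03 ± 0.16 SE). Cbln2, a synaptic organiser of the cerebellin family, fell 2.04-fold (-1.03 ± 0.14 SE), and Nrep, a protein of growing neurites, fell 1.5-fold (-0.59 ± 0.10 SE). Arpp21, a phosphoprotein of striatal projection neurons, fell 1.27-fold (-0.34 ± 0.061 SE). These 7 genes kept their call whichever array was left out, out of 27 picked by the fixed rule.

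Rises in cortex Drd1a cells whose call was lost without at least 1 array were those of Apod (2.98-fold), Trf (2.61-fold), Ifitm3, an interferon-induced membrane protein (2.53-fold), Sparc, a matricellular protein (2.08-fold), Ermn (1.91-fold) and Lipa, lysosomal acid lipase (1.6-fold). Falls whose call was lost in the same way were those of Tmem254a (2.12-fold), Prss35 (1.83-fold), Cbln1 (1.8-fold), Glra2 (1.72-fold), Angpt1, a vascular growth factor (1.61-fold), Mgp, matrix Gla protein (1.55-fold), Gadd45a, a growth arrest gene (1.51-fold), and Rab27b (1.5-fold). Drd1 (0.27 ± 0.18 SE) and Drd2 (0.72 ± 0.17 SE) were not called.

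In cortex Drd1a cells 15 of 34 lists shifted, 9 up and 6 down, and none held with an estimated correlation. Of 16 oligodendrocyte and myelin markers 3 rose and 13 were not called, with 4 risen adjusted over the list alone (median 0.28, adjusted p = 0.523 with an estimated correlation). Of 20 microglia and macrophage markers none was called, and 4 rose adjusted over the list alone (median 0.16, adjusted p = 0.523 with an estimated correlation). Of 18 interferon-induced genes Ifitm3 rose and 17 were not called, with 2 risen adjusted over the list alone, and of 11 complement and MHC class I genes none was called, with 2 risen adjusted over the list alone (each adjusted p = 0.523 with an estimated correlation). Of 28 collagens and basement membrane genes Sparc rose and 27 were not called, with 1 risen adjusted over the list alone (adjusted p = 0.725 with an estimated correlation). The astrocyte, direct-pathway, indirect-pathway and general striatal neuron lists also shifted up, with Arpp21, which fell, as the member called by limma (each adjusted p = 0.523 with an estimated correlation). Adjusted over the list alone, 4 general striatal and 1 indirect-pathway marker rose and Arpp21 fell. Of 70 mitochondrial ribosomal protein genes Mrpl42 fell (-0.38 ± 0.088 SE) and 69 were not called, with 2 fallen adjusted over the list alone (median -0.091, adjusted p = 0.281 with an estimated correlation). The immature neuron and proliferation list shifted down with Nrep fallen among 27 genes, 3 adjusted over the list alone (adjusted p = 0.523 with an estimated correlation), and its median was 0.0073 without young replicate 1. The oxidative phosphorylation, cortical glutamatergic and proteasome lists (each adjusted p = 0.523 with an estimated correlation) and the cytosolic ribosomal list (adjusted p = 0.544 with an estimated correlation) shifted down with 0 members called by limma, and adjusted over the list alone 1 proteasome gene rose. The count of called features was 21 with only these 8 arrays in the fit and 35 without the arrays with a median above 0.05. It was 15, 35 and 23 without young replicates 1, 2 and 4, and 31, 36 and 26 without old replicates 1, 2 and 4.

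**Figure D2:**
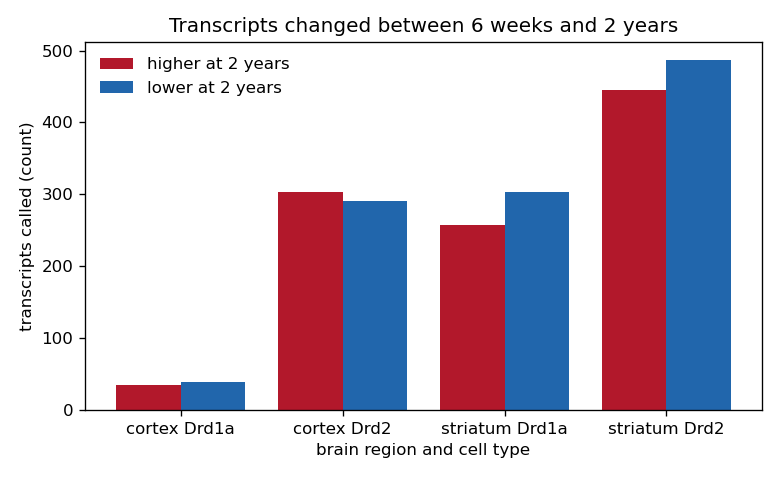
Features called higher or lower at 2 years than at 6 weeks (adjusted p of 0.05 and 1.2-fold) in each region and cell type, as counts. The counts run from 35 higher and 39 lower in cortex Drd1a cells to 445 higher and 487 lower in striatum Drd2 cells.

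**Figure D3:**
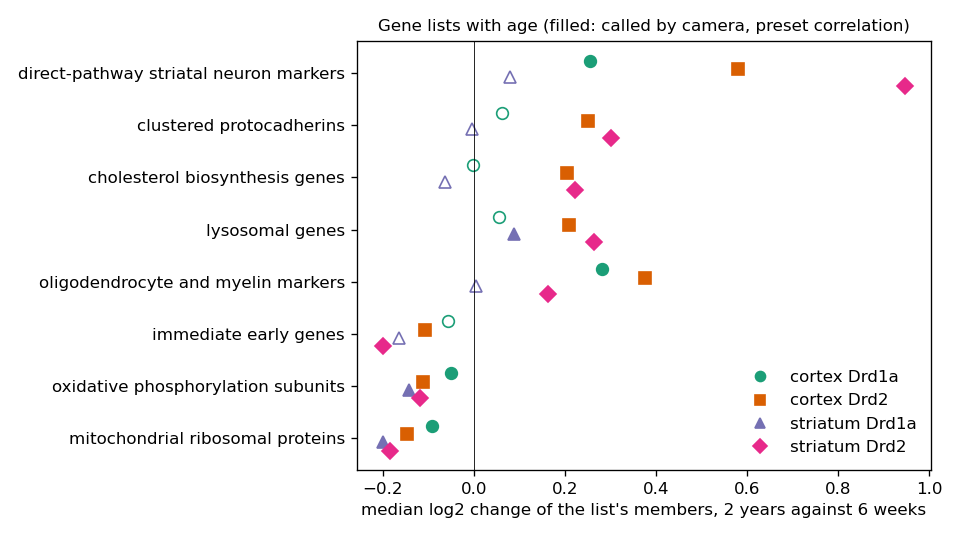
Median log2 change with age over the members of 8 gene lists in each region and cell type; filled symbols mark lists called by the competitive list test with a preset correlation. The direct-pathway markers lie at 0.95 in striatum Drd2 cells and 0.58 in cortex Drd2 cells, and the mitochondrial ribosomal proteins between -0.20 and -0.091 in all 4 comparisons.

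Across the 4 age comparisons, which share no arrays, 7 features changed in the same direction in each, against 0.000662 expected for independent lists. The labels do not say whether cortex and striatum arrays share mice, which that expectation leaves out. Tnnt2 rose by log2 changes of 0.92, 0.64, 1.13 and 1.12 in cortex Drd1a, cortex Drd2, striatum Drd1a and striatum Drd2 cells, and Ahi1, a ciliary protein, by 0.49, 0.39, 0.81 and 0.67. Fbxo9, an F-box protein, fell by 0.31, 0.43, 0.35 and 0.44 in that order, Snrpc, a U1 spliceosome protein, by 0.37, 0.30, 0.41 and 0.40, Mrpl42, a mitochondrial ribosomal protein, by 0.38, 0.35, 0.36 and 0.47, and Rps19bp1 by 0.28, 0.32, 0.37 and 0.34. At least 3 comparisons shared 110 features, 40 risen and 70 fallen, and 1 of the 1587 features called anywhere was called in both directions. Between cortex Drd2 and striatum Drd2 cells 121 features rose in both, against 8.25 expected for independent lists, and 150 fell in both, against 8.67 (exact Fisher adjusted p = 1.6e-111 and 1.75e-154; features are not independent). Spearman correlations of the age changes across features ran from 0.228 to 0.466 over the 6 pairs of comparisons. The count of 7 was 2 without young cortex Drd1a replicate 1 or 4 or old cortex Drd1a replicate 1 or 2, and 3 without young cortex Drd1a replicate 2. It was 4 without replicate 3 of young cortex Drd1a, replicate 3 or 4 of old cortex Drd1a, replicate 2 or 3 of young cortex Drd2, replicate 2 of old cortex Drd2 or replicate 2 of young striatum Drd2.

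Whether the age change differed between Drd1a and Drd2 cells was tested as an interaction, the change in Drd1a cells minus that in Drd2 cells. In the striatum 12 features differed, 4 positive and 8 negative. Drd1 rose in Drd2 preparations (2.41) and had a change of 0.11 in Drd1a preparations, a difference of -2.31 ± 0.26 SE (adjusted p = 2.9e-05). Chrm4 differed by -1.87 ± 0.27 SE, Gpr149 by -1.36 ± 0.23 SE (-2.01 with quantile normalization), Gsta3, a glutathione transferase, by -1.36 ± 0.26 SE and Tac1 by -1.30 ± 0.26 SE. Necab1, a neuronal calcium-binding protein, rose in Drd1a preparations (0.90) and had a change of -0.056 in Drd2 preparations, a difference of 0.95 ± 0.15 SE (adjusted p = 0.00414). Irak3 (0.83 ± 0.17 SE), Melk (0.69 ± 0.13 SE) and Agbl2 (0.49 ± 0.097 SE) differed the same way. In young striatum Necab1 lay at -1.55 in Drd1a and at 0.268 in Drd2 arrays. RNA of Drd2-type cells in the old Drd1a preparations was not tested as a source of its rise, and Drd2 itself was not called there. Drd1, Chrm4 and Necab1 kept their call whichever array was left out, while the count was 4 and 7 without young Drd1a replicates 1 and 3, 7 without old Drd1a replicate 3 or 4, and 5 and 7 without young Drd2 replicates 1 and 3. Without the arrays with a median above 0.05 it was 1, and the balance was 6 positive and 3 negative with quantile normalization and 8 and 6 with centred arrays.

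In the cortex 17 features differed between the cell types in their age change, 11 positive and 6 negative. Drd1 differed by -1.46 ± 0.25 SE (adjusted p = 0.0193), with changes of 0.27 in Drd1a and 1.73 in Drd2 preparations. Drc3, a ciliary dynein regulator, differed by -0.92 ± 0.16 SE, Mgp by -0.96 ± 0.20 SE, Pamr1 by -0.75 ± 0.15 SE and Sema3a, a secreted guidance cue, by -0.73 ± 0.15 SE. Psmc3ip differed by 1.32 ± 0.27 SE, Rasgrp2, a Rap exchange factor, by 0.92 ± 0.17 SE, St8sia3, a sialyltransferase, by 0.77 ± 0.15 SE, Peli2 by 0.74 ± 0.14 SE and Zfp180 by 0.66 ± 0.14 SE. None of these 10 genes kept its call through every left-out array. With only the cortex arrays in the fit limma called 0 features, and without the arrays with a median above 0.05 it called 1. With arrays centred on their medians 2 differed positively and 4 negatively, and with quantile normalization 10 and 19. The count was 11, 7 and 6 without young Drd1a replicates 1, 2 and 4, 4, 7 and 0 without old Drd1a replicates 1, 2 and 4, 1 and 6 without young Drd2 replicates 2 and 3, and 4, 3 and 34 without old Drd2 replicates 1, 2 and 4.

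Whether the age change differed between the regions was tested as the change in striatum minus that in cortex. In Drd2 cells 3 genes differed: Kcnj3 by 1.37 ± 0.20 SE (adjusted p = 0.00188), Pea15a by 1.28 ± 0.19 SE (adjusted p = 0.00188) and Satb1 by -1.15 ± 0.20 SE (adjusted p = 0.0148). In striatum these genes changed by 1.64, 1.56 and -1.07, and in cortex by 0.27, 0.29 and 0.080, where none was called. With quantile normalization the difference of Pea15a was 0.58 and its call was lost. In Drd1a cells limma called 0 features, with 1252 at an unadjusted p under 0.05. The smallest adjusted p was 0.0811, shared by Tmem159 (1.70 ± 0.34 SE), Pea15a (0.99 ± 0.20 SE), Agbl2 (0.50 ± 0.097 SE), Casp1 (-0.82 ± 0.15 SE) and Defb1 (-1.20 ± 0.23 SE). In Drd2 cells the count was 0 with only the arrays compared in the fit, 8 without young cortex replicate 3, 5 without young striatum replicate 3 or 4, and 6 without old cortex replicate 3 or 4. In Drd1a cells it was 1 without young striatum replicate 2, old cortex replicate 3 or old striatum replicate 4.

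The 2 marked cell types were also compared with each other at each age. They come from different mouse lines, so a difference could be one of cell type or of line, which the design cannot tell apart. In young striatum, Eya1, a transcriptional coactivator, was 21.6-fold higher in Drd1a cells (log2 difference 4.44 ± 0.14 SE, 3 against 4 arrays), Drd1 20.9-fold (4.38 ± 0.19 SE), Chrm4 13.1-fold (3.71 ± 0.20 SE), and the transcription factor genes Isl1 and Ebf1 7.65-fold and 6.68-fold. Ttc12, a neighbour of Drd2, was 47.0-fold lower in Drd1a cells (-5.55 ± 0.11 SE), Drd2 15.5-fold (-3.96 ± 0.19 SE), Nt5e, the ecto-enzyme that makes adenosine, 8.01-fold, Gpr6, a receptor of indirect-pathway neurons, 5.46-fold, Ankk1, which lies beside Drd2, 4.84-fold, and Penk 1.84-fold. Among markers of deep cortical layers, Foxp2, Rbp4, Crym and Sulf1 were higher and Tle4 and Vat1l lower in striatal Drd1a cells. With quantile normalization the log2 differences of Eya1, Gpr6, Drd2 and Ttc12 were 3.63, -3.05, -3.10 and -4.73. In all, 499 features differed, 275 higher and 224 lower in Drd1a cells, a balance that turned to 209 and 232 with centred arrays and to 151 and 186 with quantile normalization, and without young Drd1a replicate 1 or 3 the count was 286 or 330.

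In old striatum 459 features differed, 266 higher and 193 lower in Drd1a cells. Eya1 was 18.0-fold higher (4.17 ± 0.13 SE, n = 4 per cell type), while Drd1 was 4.21-fold higher (2.08 ± 0.18 SE), Ebf1 4.07-fold, Isl1 3.89-fold and Pdyn, the dynorphin precursor, 3.65-fold. Ttc12 was 49.4-fold lower, Drd2 14.1-fold, Ankk1 5.6-fold, Fst, an activin antagonist, 5.53-fold, Nt5e 4.58-fold and Gpr6 3.67-fold. With quantile normalization the log2 differences of Eya1, Fst and Ttc12 were 3.29, -3.29 and -5.01. Both ages shared 192 features called in the same direction in striatum.

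In young cortex 1956 features differed between the cell types, 1090 higher and 866 lower in Drd1a cells. Vip, a neuropeptide of cortical interneurons, was 15.6-fold higher in Drd1a cells (3.96 ± 0.13 SE, n = 4 per cell type), Drd1 11.1-fold, Eya1 7.69-fold, Tac2, the neurokinin B precursor, 5.05-fold and Tac1 3.82-fold. Ttc12 was 35-fold lower, Drd2 27.2-fold, Nt5e 6.99-fold, Ankk1 4.6-fold and Gpr6 4.28-fold. The layer 6 markers Tbr1 (2.94-fold), Nr4a2 (2.87-fold) and Ccn2 (2.45-fold) and the layer 5 marker Fezf2 (2.22-fold) were higher in Drd1a cells, and the layer 5 markers Vat1l (1.92-fold) and Bcl11b (1.73-fold) were lower. In old cortex 1059 features differed, 624 higher and 435 lower, with Vip 10.4-fold and Drd1 4.02-fold higher and Ttc12 35.5-fold and Drd2 16.4-fold lower in Drd1a cells. With quantile normalization the log2 differences in young cortex were 2.66 for Vip, 4.32 for Drd1, 2.24 for Eya1, 1.68 for Tac2, 3.25 for Tac1, 0.75 for Tbr1, 0.77 for Nr4a2, whose call was lost, -3.64 for Drd2 and -4.11 for Ttc12. In old cortex they were 2.58 for Vip, 3.05 for Drd1, -3.45 for Drd2 and -4.31 for Ttc12. The cortical comparisons shared 733 features in the same direction. With each array centred on its median, 452 features were higher and 564 lower in old cortex, with quantile normalization 325 and 519, and with only the old cortex arrays in the fit 618 were called.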

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

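The tests of cell admixture and of whole-tissue RNA below were chosen after the result was seen, the admixture test on genes outside the list after a first form on the list members had not decided; the searches for arrays standing apart, the interactions and the splits of the arrays were planned.

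Among 536 groups of 4 arrays, 29 had 1 array far from the other 3. The limit used flags about 1 in 20 groups of normal values by chance, which is near this count. The array median stood apart in young striatum Drd2 replicate 4 (0.0907), old cortex Drd2 replicate 1 (0.0869), young cortex Drd1a replicate 4 (-0.056) and old striatum Drd1a replicate 2 (0.134). In old striatum Drd1a replicate 2 the means of the choroid plexus markers (0.81) and the astrocyte markers (0.121) stood apart too, and in old cortex Drd1a replicate 4 the mean of the microglia markers (0.224). In cortex Drd1a arrays Psmc3ip was at -0.554 in old replicate 1, where the others lay between 0.475 and 0.538. Drd1 was at 1.19 in the same array and at 0.0703 in young replicate 1, Defb1 at 0.225 in young replicate 2, and Tac2 at 2.26 in young replicate 3. In cortex Drd2 arrays Cacng2 (-0.789), Rgs4 (-0.773) and Nt5e (0) stood apart in old replicate 1, Psap (0.147) in old replicate 2, Eya1 (-0.558) in old replicate 3, Tbr1 (0.794) in young replicate 1 and Sulf1 (-0.867) in young replicate 3. In old striatum Drd1a arrays the genes were Crabp1 in replicate 1 (0.874), Glra2 in replicate 3 (-0.726) and Spink10 in replicate 4 (-0.0594). In old striatum Drd2 arrays they were Vcan in replicate 2 (0.411), Trp53inp1 in replicate 3 (0.283), and Sulf1 (0.565), Wfs1 (0.0605) and Gadd45a (-0.0441) in replicate 4. In young striatum Drd2 arrays they were Ebf1 in replicate 3 (-0.235) and Sulf1 in replicate 4 (-0.916).

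The age change differed between Drd1a and Drd2 cells for 17 features in cortex. Of 100 splits of the arrays 1, the real one, gave as many, and the highest other gave 12. The splits redrew the age labels within each cell type, which removes age changes common to both as well. They tested whether age had any effect, so chance cannot be excluded for the interaction itself. The differences were 1.32 for Psmc3ip, 0.92 for Rasgrp2, 0.77 for St8sia3, 0.74 for Peli2, 0.66 for Zfp180, -0.73 for Sema3a, -0.75 for Pamr1, -0.92 for Drc3, -0.96 for Mgp and -1.46 for Drd1. In striatum 12 features differed, with 3 of 100 splits as high, and the same limit holds. The highest other gave 326, several times the real count, which points to structure among the arrays. The differences were 0.95 for Necab1, 0.83 for Irak3, 0.69 for Melk, 0.49 for Agbl2, -1.30 for Tac1, -1.36 for Gsta3, -1.36 for Gpr149, -1.87 for Chrm4 and -2.31 for Drd1. Between the regions 3 genes differed in Drd2 cells, Kcnj3 (1.37), Pea15a (1.28) and Satb1 (-1.15). Of 100 splits 2 were as high, and the highest other gave 3, the same as the real count. These splits also remove age changes common to both regions, so chance cannot be excluded for the interaction. In Drd1a cells limma called 0 features for the regions, with 1252 at an unadjusted p under 0.05, so all 100 splits were as high by construction and the splits decide nothing there. The highest other gave 2994, in a split whose array medians differed by -0.178 against -0.0795 in the real one.

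Direct-pathway markers rose with age in striatum Drd2 arrays, by a median of 0.947 (95% interval 0.336 to 1.81). More RNA of the whole tissue could raise each marker by an amount set by its depletion in the young preparations. No group holds whole-tissue RNA, so that amount is unknown and the marker medians cannot decide. The pooled median of glial and vascular markers was 0.0282, with endothelial markers at -0.0446 (-0.0727 to 0.00831), microglia at 0.0522 (-0.0102 to 0.126) and astrocytes at 0.0712 (0.0124 to 0.267). Oligodendrocyte markers lay at 0.164 (0.0492 to 0.378), an interval clear of the endothelial one that overlaps the others and that of the direct-pathway markers. RNA of Drd1a-type cells in the old preparations could not be decided: at the share of 22.3% that Drd1 would need, Chrm4 (1.87 predicted, 1.81 observed), Sfxn1 (1.05, 1.02) and Slc35d3 (0.946, 0.871) lay near prediction, Tac1 above it (0.98, 1.39), and Isl1 (1.3, 0.702), Pdyn (0.584, 0.142) and Eya1 (2.47, 0.336) below, a mean of -0.415 ± 0.823 (SD, exact permutation p = 0.141). Genes outside the list at least 2-fold higher in Drd1a cells (21 to 37 by halving) rose by medians of 0.213 to 0.356 where 0.292 to 0.452 was predicted, and the median difference over 6 halvings ran from -0.221 to -0.0013, with an upper bound below 0 in 2 of the 6 and a share from 16.8 to 28.1%; at limits of 0.58, 1.5 and 2 log2 units they rose by 0.156 to 0.251 (predicted 0.153 to 0.253), 0.164 to 0.668 (0.458 to 1.31) and 0.824 to 1.29 (0.835 to 1.39). A change with age within Drd2 cells stays open. The median rise of the oligodendrocyte markers was 0.164 against 0.947 for the direct-pathway markers, with intervals that overlap. The amount by which oligodendrocyte RNA alone would raise each marker is unknown too. These medians therefore cannot decide whether it was the source.

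In cortex Drd2 arrays the direct-pathway markers rose too, by a median of 0.581 (0.317 to 0.997). Whole-tissue RNA could not be decided here either, for the same reason. Endothelial markers lay at -0.0335 (-0.109 to -0.00573) and microglia at 0.0622 (0.000421 to 0.146). Astrocytes lay at 0.102 (-0.033 to 0.469) and oligodendrocytes at 0.376 (0.107 to 0.754), intervals that overlap that of the direct-pathway markers. The pooled median was 0.0235. Admixed RNA of Drd1a-type cells could not be decided: at a share of 23% Eya1 lay below prediction (1.35 predicted, 0.139 observed) and Chrm4 (0.555, 0.826) and Tac1 (0.723, 0.997) above, and the 7 other members lay a mean of -0.099 ± 0.528 (SD) from it (exact permutation p = 0.812). Genes outside the list (99 to 165) rose by 0.0833 to 0.311 where 0.372 to 0.414 was predicted, and the median difference over 6 halvings ran from -0.333 to -0.0483 with an upper bound below 0 in 5 of the 6; at limits of 0.58, 1.5 and 2 log2 units the medians were 0.0759 to 0.242 (predicted 0.221 to 0.252), -0.0113 to 0.127 (0.574 to 0.634) and 0.0285 to 0.371 (0.813 to 1.48). A change with age within Drd2 cells stays open. Across old replicates 1 to 4 oligodendrocyte markers averaged 0.77, 0.58, 0.42 and 0.082 and astrocyte markers 0.52, 0.31, 0.089 and -0.013. Direct-pathway markers averaged -0.54, -0.38, -0.32 and -0.43 there, against -1.19 to -1.01 in the young arrays. The direct-pathway means did not follow the glial means over these 4 arrays. With so few arrays this goes against a gain of glial RNA as their source without excluding it.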

How the results depend on the processing

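Leaving out the 6 arrays with a median above 0.05 was chosen after the array medians had been seen; the other alternatives were planned, and except where the construction shows it the cause of a move was not tested. Among the 308 named gene results no called gene changed sign under the alternatives run, and no called list changed direction in its test. Signs of the other called features were not followed. The medians of 4 called lists crossed 0: cholinergic (lowest -0.021) and interferon-induced (-0.0053) in cortex Drd2 without old replicate 1 or the 6 arrays, vesicle release in striatum Drd1a (-0.014) without old replicate 3, and immature neuron genes in cortex Drd1a (0.0073) without young replicate 1. The uncalled change of Drd2 ran from -0.18 to 0.48 in striatum Drd1a and from -0.074 to 0.060 in cortex Drd2 cells. Called features with age, in the order cortex Drd1a, cortex Drd2, striatum Drd1a and striatum Drd2 (74, 594, 561 and 932), moved to 21, 55, 73 and 469 with only the groups compared in the fit (fewer arrays), to 13, 52, 41 and 228 with a replicate block as well, and to 31, 131, 110 and 207 at 1.5-fold. Quantile normalization gave 23 in cortex Drd1a and 986 in cortex Drd2, array weights 330 in cortex Drd1a and 1587 in striatum Drd1a, and the first residual component as a covariate 234, 922 and 963 in cortex Drd1a, cortex Drd2 and striatum Drd1a; this component is orthogonal to the groups by construction, so only errors changed. Without the 6 arrays the counts were 35 in cortex Drd1a and 331 in cortex Drd2. The interaction with cell type in cortex (17) moved to 29 with quantile normalization, 6 with arrays centred on their medians, 0 with only the groups compared, 9 with limma-trend, 31 with array weights, 0 with the replicate block, 111 with the residual component and 1 without the 6 arrays. Limma's counts at an unadjusted p under 0.05 were 1266 in cortex and 964 in striatum. In striatum (12) it moved to 4 with only the groups compared, 7 with limma-trend, 82 with array weights, 5 with the replicate block, 37 with the residual component and 1 without the 6 arrays. The interaction with region in Drd1a cells (0) moved to 4 with quantile normalization, 4 with centred arrays, 5 with only the groups compared, 78 with array weights and 309 with the residual component. In Drd2 cells (3, with 884 at an unadjusted p under 0.05) it moved to 5 with quantile normalization, 0 with only the groups compared and 8 with array weights. Differences between the cell types in young cortex, young striatum, old cortex and old striatum (1956, 499, 1059 and 459) moved to 694, 201, 312 and 189 at 1.5-fold. With only the groups compared old cortex gave 618 and old striatum 227, and with the replicate block young striatum, old cortex and old striatum gave 223, 473 and 234. Array weights gave 852 in young striatum and 1137 in old striatum, the residual component 1624 in old cortex, and leaving out the 6 arrays 312 in young striatum. Features shared by all 4 age comparisons (7) moved to 4 with quantile normalization, 2 with only the groups compared, 33 with array weights, 2 at 1.5-fold, 2 with the replicate block and 24 with the residual component. Lists shifted (15, 17, 8 and 12) came to 0, 1, 0 and 5 with an estimated correlation and to 0, 8 and 2 by fry in the first 3 comparisons. With each array left out in turn the counts ran from 15 to 63 in cortex Drd1a, 176 to 843 in cortex Drd2 and 170 to 636 in striatum Drd1a, from 0 to 34 and 4 to 16 for the cell type interactions in cortex and striatum, 0 to 1 and 2 to 8 for the region interactions in Drd1a and Drd2 cells, 286 to 490 between cell types in young striatum, 2 to 10 for shared features and 4 to 10 for lists in striatum Drd1a. Scaling moved the balance of higher and lower counts: 15 and 8 in cortex Drd1a, 270 and 174 in striatum Drd1a, 10 and 19 and 6 and 3 for the cell type interactions in cortex and striatum, 2 and 3 for the region interaction in Drd2 cells, 151 and 186 in young striatum and 325 and 519 in old cortex between cell types with quantile normalization, and 354 and 177 in cortex Drd2, 364 and 170 in striatum Drd1a, 2 and 4 and 8 and 6 for the cell type interactions and 452 and 564 in old cortex with centred arrays. Of 308 named gene results, the call was lost for 140 with only the groups compared, 147 with the replicate block, 93 at 1.5-fold, 85 without the 6 arrays, 56 with quantile normalization, 38 with centred arrays, 20 with limma-trend, 16 with array weights and 5 with the random block (correlation -0.0635), and for 0 without a fold threshold or with the residual component. Quantile normalization moved the fold of 32 of the 308 by more than 1.5 times and each other alternative, leaving out arrays included, that of 0. It acted on values already centred per feature, so these moves are not those of a normalization of the array signal. Changes of threshold alone leave the fold as it is. The filter on dim features and the sex covariate were not run. Limma-trend has no absolute level to follow in these centred values, and the array's signal over background, which limits small changes, was not measured here.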

Other observations

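The tests of neighbouring genes and of the array median below were chosen after the result was seen; the splits of the arrays were planned.

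Other splits of the same arrays were counted for the age comparisons. The real split gave the highest count of genes in cortex Drd1a cells (74, highest other split 1), cortex Drd2 cells (594, highest other 105) and striatum Drd2 cells (932, highest other 15). Each had 1 of 35 splits as high, a share of 0.0286, the smallest possible and not adjusted over the comparisons. This argues against chance there without excluding it. The splits do not argue against chance for striatum Drd1a cells, where 2 of 35 were as high: the exchange of old replicate 2 and young replicate 2 gave 1405 against 561. The array medians differed by -0.12 in that split and by -0.0415 in the real one, and the high count points to a structure among the arrays whose cause was not tested. In the real split 429 features were called without the 6 arrays with a high median, and 300 of them were among the 561. That setting removes old replicate 2 and young replicate 3 from this comparison. For gene lists chance cannot be excluded in cortex Drd1a cells (15, highest other 16, 2 of 35), striatum Drd1a cells (8, highest other 13, 17 of 35) or striatum Drd2 cells (12, highest other 12, 2 of 35). In cortex Drd2 cells 1 of 35 splits was as high, a share of 0.0286, the smallest that 35 splits can give. Another split called 16 lists against 17 there, so the count barely sets the real split apart. For the 7 features changed in all 4 comparisons 1 of 100 splits was as high, and the highest other gave 0. These splits removed the age changes of every comparison at once. They argue against an absence of any age effect, and cannot test whether true changes overlap by chance.

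Between Drd1a and Drd2 cells the real split gave the highest count in young cortex (1956, highest other 6), young striatum (499, highest other 142) and old cortex (1059, highest other 252), each with 1 of 35 splits as high. This argues against chance there without excluding it, and the splits cannot part cell type from mouse line. In old striatum the count does not argue against chance, with 2 of 35: the exchange of Drd1a replicate 2 and Drd2 replicate 4 gave 1990 against 459, with array medians differing by -0.117 against -0.0137. The first component of the residual spread held 30.1% of it and followed the array median (Pearson correlation 0.939).

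Of 4 genes adjacent to Drd2 or Drd1, 2 (Ankk1 and Sfxn1) were called in the receptor's direction in all 4 comparisons of the preparations, and of 16 genes 2 to 5 places away 1 was, Ttc12. A candidate explanation is extra copies of neighbouring genes carried by the transgenes of the mouse lines, which the labels do not describe. It stays open: Ankk1 and Ttc12 prompted the question, Sfxn1 is also a direct-pathway marker, and of the other 2 adjacent genes 0 were called in all 4 comparisons by limma. Shared regulation of neighbouring genes in these cells was not tested.

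The median change of the mitochondrial ribosomal protein transcripts was below 0 in all 4 age comparisons, with 1, 7, 14 and 15 of 70 members fallen, and the list call held with an estimated correlation in striatum Drd2 cells (adjusted p = 0.0277) and not in cortex Drd1a, cortex Drd2 or striatum Drd1a cells (adjusted p = 0.281, 0.136 and 0.0782). Array-wide differences that follow the array median are argued against as the whole cause. Within groups the slope of their mean on the array median was -0.227 ± 0.151 (SE), whereas slopes of -2.33, 9.07, 4.99 and 17 would be needed for the whole shift in cortex Drd1a, cortex Drd2, striatum Drd1a and striatum Drd2 cells. Old and young medians differed little (0.0381, -0.0152, -0.0415 and -0.011), so the shifts with the median as a covariate, -0.08 ± 0.0316, -0.141 ± 0.0311, -0.216 ± 0.0341 and -0.189 ± 0.0311 (SE), lay close to those without it. In old cortex Drd2 replicates 1 to 4 the list averaged -0.23, -0.14, -0.11 and -0.023, where astrocyte markers averaged 0.52, 0.31, 0.089 and -0.013. Whether the fall there followed the glial rise was not tested. A change with age in these cells and array differences of other kinds stay open, untested.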
